A study of Homo sapiens with 43 samples.

How the data were processed

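RNA was measured in 43 libraries of HPAF-II tumours, a human graft in a mouse host, in 7 groups by time on ETC-159. The vehicle group at 0h held 7 libraries and each of the 6 later times held 6. Groups and replicate numbers were taken from the sample titles and time labels. RNA was extracted with a column kit and polyA libraries were made with a stranded kit, per the labels' protocols.

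Reads were trimmed with cutadapt, aligned with STAR and counted with RSEM on hg38, per the submitters' processing notes. Tool versions, the annotation release, the strand setting and the handling of reads from the mouse host are not given in the sources used here. The deposited tables hold RSEM expected counts and TPM per gene, per the file headers. Expected counts are estimates that share reads between genes, and between 4.53% and 5.38% of genes per library had a value that was not whole. The tables listed 60499 genes, and 56321 of them matched a symbol in GENCODE v44 on GRCh38, from which names, biotypes and coordinates were taken.

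Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. TMM normalisation was used, with factors between 0.889 and 1.08, and filterByExpr by group left 16715 genes. A quasi-likelihood model with 1 term per group was fitted over all 43 libraries, and each time was compared with 0h. Contrasts of 8h with 3h, 56h with 8h and 7d with 56h were also made, with a joint test of the 6 times. Adjusted p-values follow Benjamini and Hochberg within a contrast, and 0.05 was the threshold. The standard error of a log2 fold change was its size divided by the square root of F. CPM values are counts scaled to a fixed library total with TMM normalisation, and error terms of CPM and shares are SDs over libraries. The common biological coefficient of variation was 0.218. Totals lay between 17172182 and 32991090 counts with a median of 25473714, and between 20517 and 22896 genes had a count. Gene-wise tests of CPM under 1 rest on few reads.

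There were 33 lists of genes fixed before the data were examined. They cover Wnt targets, Wnt ligands and secretion, Wnt receptors and core components, MYC targets, ribosome biogenesis, ribosomal proteins, mitochondrial ribosome, S phase, G2/M, CDK inhibitors and quiescence, homologous recombination, epithelial secretory differentiation, MAPK feedback, immediate early genes, p53 targets, hypoxia and glycolysis, interferon response, unfolded protein response, cholesterol synthesis, oxidative phosphorylation, mesenchymal genes, YAP targets, Notch targets, lysosome and autophagy and the circadian clock. Markers of acinar cells, stroma, endothelium, leukocytes, erythroid cells and islets were included, as were mitochondrially encoded and replication-dependent histone genes as signs of RNA quality. Lists with at least 5 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 174 tests, and again with an estimated correlation and with fry. Values of fry are printed only for some lists. A list score is the mean log2 CPM of its measured members in a library minus the 0h mean. Shares of counts, library totals and RIN were compared with 0h by exact two-sided permutation tests of 1716 splits, adjusted over 54 tests, for which the smallest p is 0.000583.

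Genes named in the text follow a rule fixed in advance. It takes 10 Wnt pathway genes at every time (AXIN2, LGR5, RNF43, ZNRF3, NKD1, NOTUM, MYC, CCND1, PORCN and WLS). It adds the 6 largest rises and 6 largest falls at each time, and the 4 largest each way between treated times, among called protein-coding genes with a mean of at least 5 CPM in the higher group and groups that do not overlap. It also adds up to 4 members of each called list in its direction and 1 in the other. Groups of 7 and 6 libraries do not overlap in 0.117% of genes by chance. Genes outside the rule are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

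Alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, replicate number as a block, RIN as a covariate, libraries with RIN under 7 left out, the style of sample naming in the deposited data as a covariate or alone, the DESeq2 1.42.0 test, limma on log2(TPM + 1), a fit of only the groups compared and a minimum log2 fold change of 1. Leaving out each library in turn was chosen after seeing the data, as was the repeat of lists and named genes without the library labelled 3h replicate 6, of lists without 16h replicate 2, and of list members and named genes at its own time without each library that stood apart in a list score. The deposited TPM values were used only in alternatives, with no further scaling between libraries.

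The tests were checked on simulated data before use. For 8h against 0h with 16715 genes, edgeR recovered 62.7% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 4 false calls. Genes were simulated independently of each other, so these figures do not give the error rate where genes vary together between tumours. No pair of replicates agreed within sampling noise, with a lowest chi-square per degree of freedom of 3.99 over 111 pairs, so each library was counted once.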

Results

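Gene expression was measured in tumours of HPAF-II, a human pancreatic adenocarcinoma line with a mutant RNF43 gene, grown in the pancreas of mice for 28 days. RNF43 is a ubiquitin ligase that removes Wnt receptors from the cell surface. The mice then received ETC-159, an inhibitor of PORCN, on a schedule the labels give as bid. PORCN is the acyltransferase that adds the lipid Wnt ligands need for secretion. Tumours of a vehicle group at 0h (n = 7) and of animals treated for 3 h, 8 h, 16 h, 32 h, 56 h or 7 days (n = 6 each) gave 43 libraries of polyA RNA. Each held between 17172182 and 32991090 counts, and 16715 genes were tested. The comparisons ask how transcription in the tumour followed inhibition of Wnt secretion over time. No vehicle group was sampled at the later times, so time on the drug and time itself could not be separated in any comparison with 0h. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries.

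The number of genes that differed from the vehicle group was small at 3h and large from 32h on. By edgeR's quasi-likelihood test at an adjusted p under 0.05, 4 genes were higher and 0 lower at 3h, where 1394 genes had an unadjusted p under 0.05 and DESeq2 called 32. At 8h 701 genes were higher and 805 lower, and at 16h 1705 were higher and 1423 lower. The counts were 3893 and 3662 at 32h, 3273 and 3737 at 56h, and 3642 and 3929 at 7d. Genes that also changed by at least 1 on the log2 scale numbered 141 at 8h, 500 at 16h, 1717 at 32h, 1672 at 56h and 1861 at 7d. A joint test of the 6 times called 10359 genes, 62% of those tested. On log2(TPM + 1) with limma, where the median of all genes lay at -0.18 at 8h and -0.17 at 32h, 0 genes were higher and 2 lower at 3h, 177 and 3921 at 8h, 631 and 2384 at 16h, and 1546 and 6132 at 32h. The edgeR count at 8h was 419 without the 3 libraries of RNA integrity number (RIN) under 7. It was 779 without 8h replicate 3, 930 without 8h replicate 4, 941 without 8h replicate 5, 981 without 0h replicate 4, 951 without 0h replicate 5 and 878 without 0h replicate 6.

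**Figure D1:**
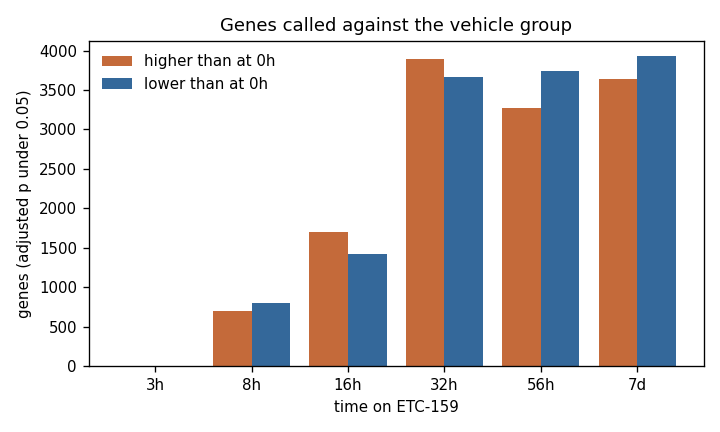
Number of genes with an edgeR adjusted p under 0.05 at each time on ETC-159 against the vehicle group, with bars for genes higher and lower than at 0h. The bars go from 4 and 0 genes at 3h to 3642 and 3929 genes at 7d.

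Wnt target genes were lower from 8h on. AXIN2, a scaffold of the complex that degrades beta-catenin (ENSG00000168646, GRCh38 chromosome 17, 65528563 to 65561648), stood at 28.9 ± 4.52 CPM (SD, n = 7) at 0h. It was 6.18 ± 0.843 CPM (n = 6) at 8h, a log2 fold change of -2.22 ± 0.27 (SE; adjusted p = 8.41e-07), 2.55 ± 0.59 at 16h and 1.05 ± 0.472 at 32h. At 7d it was 1.05 ± 0.316 CPM, with a log2 fold change of -4.77 (adjusted p = 5.16e-14). NKD1, an antagonist that binds Dishevelled (ENSG00000140807, chromosome 16, 50548396 to 50649249), went from 39.9 ± 10.3 CPM at 0h to 11.5 ± 4.38 at 8h, with a log2 fold change of -1.79, and was at 2.57 ± 0.777 CPM at 7d. NOTUM, the enzyme that takes the lipid off secreted Wnts (ENSG00000185269, chromosome 17, 81952507 to 81961840), had a log2 fold change of -0.70 at 8h (adjusted p = 0.2), with 4.27 to 6.9 CPM in the 6 libraries against 7.83 to 11.4 in the 7 at 0h. Without the library labelled 3h replicate 6, which is in neither group, NOTUM passed at 8h (adjusted p = 0.0187), with adjusted p between 0.00856 and 0.412 over its alternatives. It fell by 2.00 at 16h, by 4.90 at 32h and by 5.75 at 7d on the log2 scale. RNF43 itself (ENSG00000108375, chromosome 17, 58353676 to 58417595) fell from 100 ± 24.1 to 65.9 ± 16.9 CPM at 8h (adjusted p = 0.0367) and was at 37.2 ± 3.3 CPM at 7d. The 8h call of RNF43 was lost without the libraries of RIN under 7 (adjusted p = 0.169), without 8h replicate 3 (adjusted p = 0.0956) and without a filter on low counts (adjusted p = 0.0548), with adjusted p between 0.00316 and 0.169 over its alternatives. ZNRF3, the paralogous ligase (chromosome 22, 28883572 to 29057488), fell by 1.17 at 8h and by 1.87 at 7d. LGR5, the R-spondin receptor, was low throughout: 1.82 ± 0.514 CPM at 0h and 0.17 ± 0.162 at 16h (adjusted p = 2.04e-05).

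Of 19 measured genes in a list of Wnt targets, 9 fell at 8h, 15 at 16h, 16 at 32h and at 56h and 15 at 7d, and 1 rose at 56h and at 7d. Adjusted over the list alone the numbers were 13, 16, 16, 16 and 15. The 9 at 8h were 5 without the libraries of RIN under 7, 5 without 8h replicate 3, 13 without the library labelled 3h replicate 6 and 16 on log2(TPM + 1). The median log2 fold change of the list was -0.71 at 8h, -1.36 at 16h and -1.43 at 7d. The list was lower than other genes by camera at every time, and from 8h on also with an estimated correlation (adjusted p = 0.0201 at 8h, 0.00171 at 16h, 0.00782 at 32h, 0.0122 at 56h and 0.0201 at 7d). At 3h the estimated correlation gave an adjusted p = 0.312. Without the library labelled 3h replicate 6 the 3h median was -0.08 in place of -0.21, and camera at the preset correlation gave an adjusted p = 0.0292. Other members that fell included SP5, a transcription factor, with a log2 fold change of -1.89 at 8h and -2.25 at 16h, and BMP4, a bone morphogenetic protein, with 341 ± 22.4 CPM at 0h and 160 ± 14.5 at 16h. The members CD44 and DKK1, chosen after their values were seen, did not pass at 7d (log2 fold changes of 0.16 and -0.32). CCND1, the gene of cyclin D1, went from 355 ± 27.4 CPM at 0h to 215 ± 34.7 at 32h (adjusted p = 4.4e-07) and stood at 363 ± 41 CPM at 7d (log2 fold change 0.03, adjusted p = 0.834). MYC, the transcription factor of cell growth, fell by 0.58 at 16h, by 0.95 at 32h and by 1.27 at 7d.

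**Figure D2:**
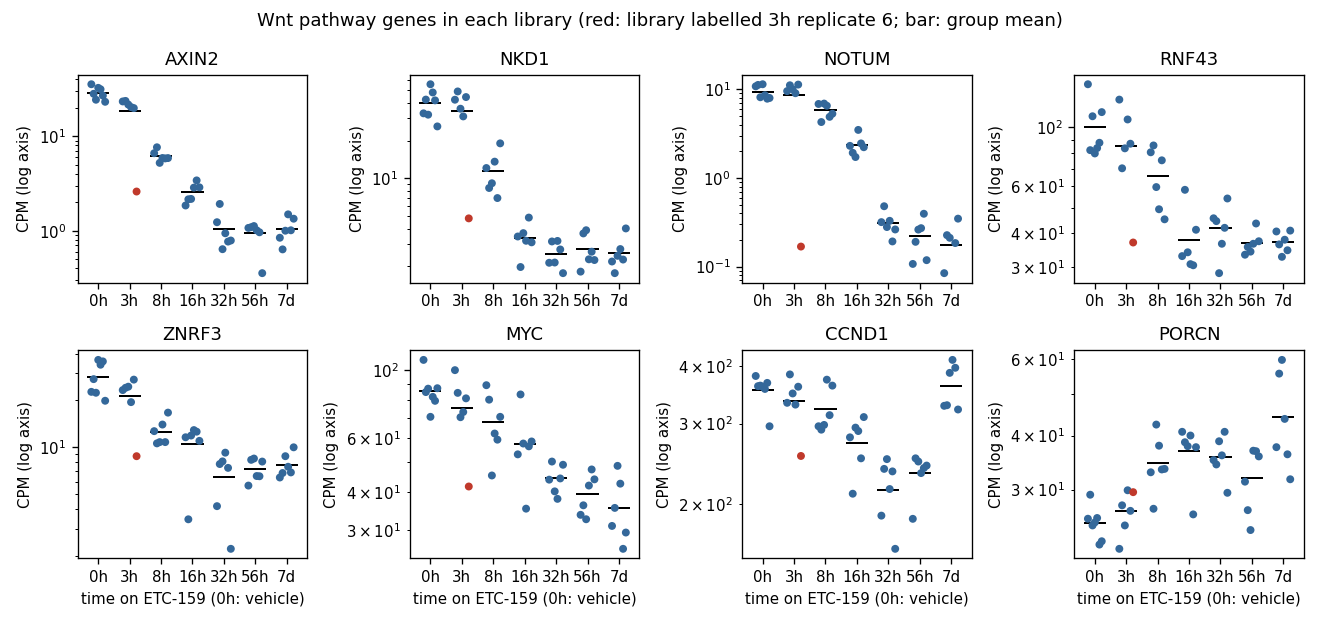
CPM of 8 Wnt pathway genes in each library on a log axis, by time on ETC-159, with a bar at each group mean. AXIN2 goes from 28.9 CPM at 0h to 1.05 CPM at 7d, and the library labelled 3h replicate 6 (red) lies at 2.6 CPM.

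Of 11 measured genes of Wnt ligands and of their secretion, 4 rose and 0 fell at 8h, and 7 rose and 2 fell at 7d. Adjusted over the list alone 6 rose and 1 fell at 8h, and 7 rose and 2 fell at 7d. WNT7B, a Wnt ligand, went from 55 ± 2.87 CPM at 0h to 86.5 ± 12.3 at 8h (log2 fold change 0.65 ± 0.09, adjusted p = 1.23e-05). WNT7A went from 1.63 ± 0.419 to 3.54 ± 0.595 CPM and WNT2B from 1.95 ± 0.391 to 3.58 ± 0.573 CPM (adjusted p up to 0.0559 over the alternatives of WNT2B). PORCN, the drug's target (chromosome X, 48508959 to 48520814), went from 25.1 ± 2.25 CPM to 34.5 ± 5.16 at 8h (adjusted p = 0.0149) and to 44.1 ± 11.3 at 7d (log2 fold change 0.81, adjusted p = 1.7e-06). Without the libraries of RIN under 7 the 8h value of PORCN was 0.44 with an adjusted p = 0.085, and without 8h replicate 3 it was 0.39 with an adjusted p = 0.0679, within 0.00651 and 0.207 over its alternatives. WLS, the carrier of Wnts to the cell surface, fell by 0.32 at 16h and by 0.39 at 32h and did not pass at 7d (log2 fold change -0.10). Camera called the list up at 8h (adjusted p = 0.000183) and 7d (adjusted p = 0.000807), but with an estimated correlation the values were adjusted p = 0.0973 and adjusted p = 0.14. Of 24 measured receptors and core components of the pathway, 8 rose and 6 fell at 7d, also adjusted over the list alone, and camera did not call that list at any time.

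At 3h the 4 genes called were EPHA2, LRRC8A, PLK3 and GMFG. EPHA2, an ephrin receptor, went from 157 ± 12.8 CPM at 0h to 213 ± 15.3 (log2 fold change 0.44 ± 0.07, adjusted p = 0.00761). LRRC8A, a subunit of a volume-regulated anion channel, rose by 0.46 and PLK3, a polo-like kinase, by 0.53. GMFG, with 0.965 CPM at 0h and 2.65 CPM at 3h, lies below the level set for named genes and was chosen after its value was seen (log2 fold change 1.46, adjusted p = 0.02). The library labelled 3h replicate 6 did not resemble the other 5 at 3h. It had 2.6 CPM of AXIN2 against 19.9 to 23.7 in the others, 0.168 CPM of NOTUM against 9.03 to 11.3, and 4.82 CPM of NKD1. Without it 1 gene passed at 3h, EPHA2 (211 ± 16.2 CPM, n = 5; adjusted p = 0.0385), while LRRC8A had an adjusted p = 0.0688 and PLK3 an adjusted p = 0.147. Over all alternatives adjusted p went up to 0.158 for EPHA2, 0.231 for LRRC8A and 0.209 for PLK3. AXIN2 was then at 21.8 ± 1.7 CPM (log2 fold change -0.41, adjusted p = 0.948). The count at 3h was 15 without 3h replicate 5, 13 without 3h replicate 3, 7 without 3h replicate 1, 2 without 0h replicate 4 and 2 without 0h replicate 6. RIN was also higher in all 6 libraries at 3h (mean 8.7) than in any at 0h (mean 7.47; exact two-sided permutation p = 0.00117, adjusted p = 0.00899).

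Among lists, the feedback inhibitors and targets of MAPK signalling were higher at 3h. Of 21 members 1 rose, EPHA2, and 7 when adjusted over the list alone, with a median log2 fold change of 0.19. Camera gave an adjusted p = 3.88e-08, and adjusted p = 0.00288 with an estimated correlation. Camera called 11 lists at 3h, 4 up and 7 down. None of the other 10 held with an estimated correlation, which included the S phase list (adjusted p = 0.508), the G2/M list (adjusted p = 0.56), the homologous recombination list (adjusted p = 0.444), MYC targets (adjusted p = 0.917) and the mitochondrial ribosome list (adjusted p = 0.917). No member of these 5 lists fell at 3h. Without the library labelled 3h replicate 6 the median of the S phase list was -0.17 in place of -0.35, and that of G2/M -0.15 in place of -0.35. The genes of Wnt ligands and secretion were among the lists called up at 3h (3 of 11 adjusted over the list alone), with an adjusted p = 0.0973 with an estimated correlation.

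At 8h the largest falls by the rule for named genes were those of AXIN2, EDAR, SP5, NKD1, MYB and EPHB3. EDAR, the ectodysplasin receptor, went from 19.7 ± 2.11 to 4.99 ± 2.23 CPM, and EPHB3, an ephrin receptor of the intestinal crypt, from 226 ± 44.3 to 76.5 ± 9.13 CPM (adjusted p = 8.94e-08). MYB, a transcription factor of progenitor cells, went from 7.17 ± 2.42 to 2.27 ± 0.644 CPM. The largest rises by the rule were those of ANGPTL4 (log2 fold change 1.26), MT-ND6 (1.26), DUSP5 (1.23), CDKN2B (0.97), PHACTR3 (0.96) and PLAU (0.93). DUSP5, a phosphatase of ERK, went from 47.9 ± 8.13 to 113 ± 14.2 CPM, and CDKN2B, the inhibitor of CDK4 and CDK6, from 69.1 ± 3.69 to 136 ± 12.8 CPM. PLAU, the urokinase gene, went from 149 ± 24.6 to 283 ± 45.4 CPM.

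Interferon response genes were higher on average at 8h. Of 35 members 17 rose and 0 fell, and 27 rose when adjusted over the list alone, with a median log2 fold change of 0.42. The list scores of 8h replicates 4 and 6, 0.22 and 0.17, lay within the -0.29 to 0.31 of 0h. IRF7, a transcription factor of the response, went from 89.7 ± 13.8 to 149 ± 17.9 CPM (adjusted p = 0.000133), IFIT3 from 89.7 ± 15.8 to 144 ± 30.5 and IRF9 from 153 ± 9.72 to 188 ± 8.44 CPM (adjusted p up to 0.344 over the alternatives of IRF9). Camera gave an adjusted p = 2.02e-16, but adjusted p = 0.343 with an estimated correlation. All 13 mitochondrially encoded genes rose at 8h, with a median log2 fold change of 0.81 (camera adjusted p = 1.77e-12; adjusted p = 0.308 with an estimated correlation). The 13 also passed adjusted over the list alone. MT-ND2 went from 3250 ± 877 to 6380 ± 3020 CPM and MT-ND1 from 4170 ± 1110 to 8060 ± 4090 CPM. Without the libraries of RIN under 7 (8h replicates 4 and 5 and 32h replicate 1) 0 of the 13 passed and the median was 0.45, and 9 of the 35 interferon genes passed with a median of 0.46. With RIN as a covariate all 13 passed with a median of 0.73, and 17 interferon genes passed with a median of 0.42. On log2(TPM + 1) 8 of the 13 and 5 of the 35 passed, and without 8h replicate 3, 10 of the 13 and 11 of the 35 did. RIN at 8h lay between 5.6 and 9.1, with a mean of 7.47 at 8h and at 0h. The mitochondrially encoded share of counts exceeded all 0h libraries only in 8h replicates 3, 4 and 5, those of lowest RIN. In the unfolded protein response list 5 of 24 rose at 8h, 1 without the libraries of RIN under 7 and 0 without 8h replicate 3 (8 adjusted over the list alone; adjusted p = 0.603 with an estimated correlation), and on log2(TPM + 1) 0 rose and 2 fell. In the hypoxia and glycolysis list 2 of 28 rose, ANGPTL4 and PFKP (adjusted p up to 0.744 over the alternatives of PFKP), and 4 when adjusted over the list alone (adjusted p = 0.668 with an estimated correlation), and the median of that list was 0.22 by edgeR. In the hypoxia list 1 rose and 2 fell on log2(TPM + 1), with a median of -0.04. The library 8h replicate 3 had a score of 0.76 for this list against 0.15 to 0.22 in the others, and without it the same number rose, 2, and the median was 0.12. MAPK feedback genes rose in 5 of 21 cases at 8h, in 3 without the libraries of RIN under 7, with a median of 0.07 by edgeR. Adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.275 with an estimated correlation). In the MAPK list 2 rose and 6 fell on log2(TPM + 1), with a median of -0.17. On that scale the median of all genes at 8h was -0.18, so list values there are to be read against it. The MAPK median lay near it and the hypoxia median above it. Of 78 ribosomal protein genes 0 passed at 8h, also adjusted over the list alone, although camera called the list up (adjusted p = 1.96e-06; adjusted p = 0.865 with an estimated correlation), and its median of 0.16 was -0.07 on log2(TPM + 1). No S phase gene passed at 8h either, and 3 of 35 homologous recombination genes fell, 4 adjusted over the list alone, while camera called both lists down (adjusted p = 0.835 and adjusted p = 0.726 with an estimated correlation).

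Of 55 MYC targets 28 fell and 1 rose at 16h, and 42 fell when adjusted over the list alone, with a median log2 fold change of -0.38. Camera gave an adjusted p = 1.03e-14, but adjusted p = 0.508 with an estimated correlation. UNG, the uracil DNA glycosylase, went from 61.4 ± 7.85 to 31.7 ± 7.12 CPM, SLC19A1, a folate carrier, from 19.8 ± 1.63 to 11 ± 2.45, and NOLC1, a nucleolar protein, from 125 ± 9.37 to 80.4 ± 18.2 CPM. HK2, a hexokinase, was the member that rose (log2 fold change 0.57; adjusted p up to 0.195 over its alternatives). Of 57 ribosome biogenesis genes 21 fell (28 adjusted over the list alone), among them DKC1, the pseudouridine synthase, from 143 ± 7.64 to 90.1 ± 22.1 CPM (list adjusted p = 0.622 with an estimated correlation). Of 46 S phase genes 31 fell and 41 did so when adjusted over the list alone, with a median of -0.73 (camera adjusted p = 1.48e-14; adjusted p = 0.56 with an estimated correlation). Of 41 G2/M genes 0 passed in either direction at 16h, and their median was -0.02. With naming style as a covariate 14 MYC targets and 15 S phase genes fell at 16h. On log2(TPM + 1), where the median of all genes at 16h was -0.09, 39 ribosome biogenesis genes fell. The library 16h replicate 2 had the lowest score of the MYC targets at 16h, -1.06 against -0.43 to -0.11 in the others. Without it 13 MYC targets, 8 ribosome biogenesis genes, 11 S phase genes and 1 homologous recombination gene fell, with medians of -0.28, -0.16, -0.64 and -0.39, and HK2 did not pass (adjusted p = 0.104). Camera then called 8 lists in place of 11. Homologous recombination genes fell in 5 of 35 cases at 16h, 15 on log2(TPM + 1) and 9 adjusted over the list alone (adjusted p = 0.68 with an estimated correlation).

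In the cholesterol synthesis list 13 of 24 rose and 0 fell at 16h, 17 adjusted over the list alone, with a median of 0.51 (adjusted p = 0.622 with an estimated correlation). HMGCS1, the synthase before HMG-CoA reductase, went from 125 ± 21 to 238 ± 67.9 CPM. In the unfolded protein response list 11 of 24 rose, 13 adjusted over the list alone (camera adjusted p = 3.03e-08; adjusted p = 0.27 with an estimated correlation). HSPA5, the chaperone BiP, went from 558 ± 39.7 to 931 ± 163 CPM (adjusted p = 4.72e-06) and CALR, calreticulin, from 609 ± 21.5 to 834 ± 115 CPM. Epithelial secretory genes rose in 13 of 39 cases at 16h, 13 adjusted over the list alone (adjusted p = 0.622 with an estimated correlation). Without 16h replicate 2, 9 epithelial genes rose and 2 fell, and the median was 0.26 in place of 0.46. Of 20 inhibitors of cyclin-dependent kinases and quiescence genes 6 rose, and 6 adjusted over the list alone. CDKN2B reached 167 ± 32.8 CPM and CDKN1B, the gene of p27, went from 39.4 ± 2.17 to 47 ± 3.35 CPM (list adjusted p = 0.618 with an estimated correlation), with adjusted p up to 0.315 over the alternatives of CDKN1B. The library 16h replicate 2 had a score of 0.74 for this list against -0.1 to 0.17 in the others. Without it 5 members rose and 1 fell, the median was 0.12 in place of 0.23, and camera gave an adjusted p = 0.0837 in place of 0.00772. With naming style as a covariate 7 epithelial genes rose at 16h. On log2(TPM + 1) 8 epithelial genes, 3 cholesterol synthesis genes and 2 of the inhibitors and quiescence genes did. By the rule for named genes, which asks for a mean of 5 CPM in the higher group, the largest rises were those of RAB37 (log2 fold change 2.19), ALPP (2.13), KLHL30 (1.82), SMPD3 (1.68), PHACTR3 (1.65) and AKR1B10 (1.63). The largest falls by that rule besides NKD1 and AXIN2 were those of IL10 (-2.70), EDAR (-2.40), INHBB (-2.30) and ATOH8 (-2.28), and LGR5, below that level, fell by 3.36. INHBB, an inhibin subunit, went from 33.4 ± 11.4 to 6.77 ± 1.95 CPM.

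At 32h and 56h genes of the cell cycle were lower across their lists. All 46 S phase genes fell at both times, with medians of -1.76 and -2.08, and the 46 all fell when adjusted over the list alone. RRM2, the small subunit of ribonucleotide reductase, went from 202 ± 18.1 CPM at 0h to 21.1 ± 4.68 at 56h (log2 fold change -3.26 ± 0.32, adjusted p = 5.27e-10), and TK1 from 66.4 ± 10.9 to 10.4 ± 2.15 CPM. Of 41 G2/M genes 40 fell at both times, with medians of -1.49 and -2.72, and 40 adjusted over the list alone. CDK1, the mitotic kinase, went from 83.5 ± 9.91 to 11 ± 2.52 CPM, CCNA2 from 53.4 ± 8.16 to 7.05 ± 1.02 and NUSAP1 from 89.5 ± 13.2 to 11.8 ± 2.56 CPM at 56h. Of 35 homologous recombination and Fanconi genes 31 fell at 32h and 29 at 56h, 33 and 29 adjusted over the list alone. BLM, a helicase, went from 12.2 ± 2.61 to 1.47 ± 0.356 CPM at 56h. At 56h camera gave adjusted p = 8.5e-44 for S phase, adjusted p = 3.26e-48 for G2/M and adjusted p = 2.21e-22 for homologous recombination. With an estimated correlation these were adjusted p = 0.14, adjusted p = 0.0973 and adjusted p = 0.222. At 32h they were adjusted p = 0.241, adjusted p = 0.444 and adjusted p = 0.27.

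**Figure D3:**
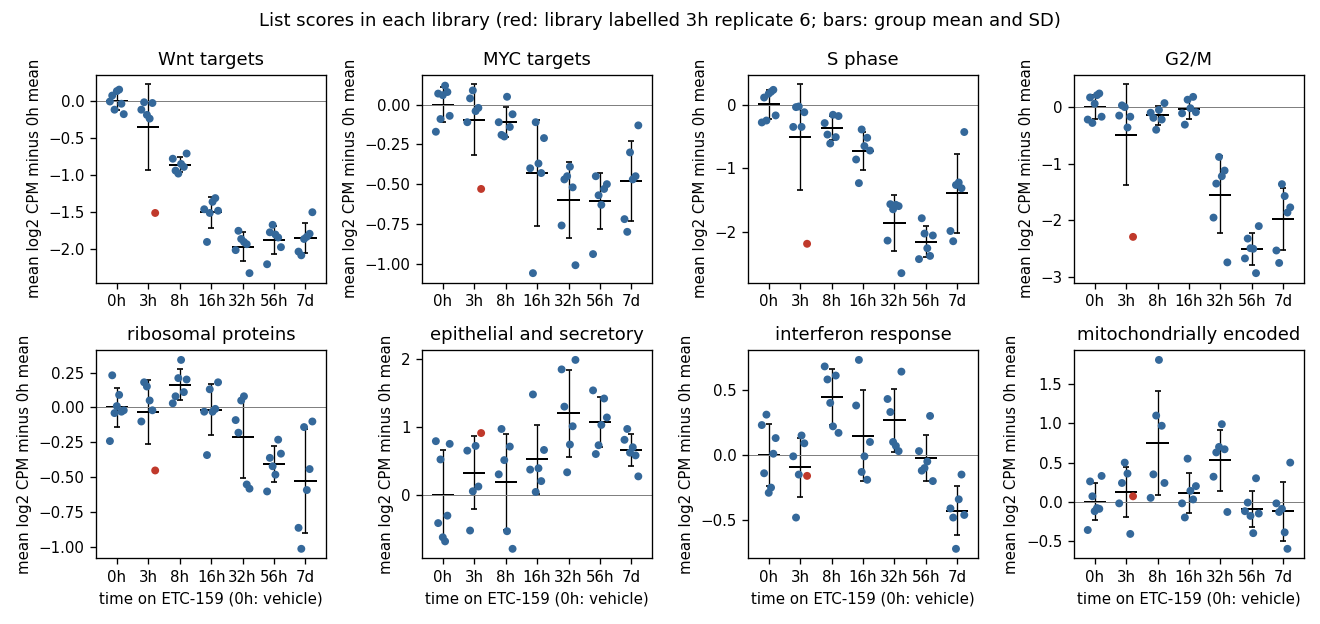
Mean log2 CPM over the measured members of 8 lists, minus their mean at 0h, in each library by time on ETC-159, with bars for the group mean and SD. The library labelled 3h replicate 6 (red) lies at -1.51 for Wnt targets and -2.29 for G2/M, outside the other 3h libraries.

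Of 55 MYC targets 45 fell at 32h and 50 at 56h (48 and 53 adjusted over the list alone; adjusted p = 0.56 at both times with an estimated correlation). Ribosome biogenesis genes fell in 40 of 57 cases at 32h and in 36 at 56h (44 and 37 adjusted over the list alone; adjusted p = 0.622 and adjusted p = 0.739 with an estimated correlation). Of 78 ribosomal protein genes 0 passed at 16h, 18 fell at 32h, 63 at 56h and 74 at 7d. Adjusted over the list alone these were 0, 0, 68 and 75. With naming style as a covariate 0 fell at 32h, 13 at 56h and 41 at 7d. On log2(TPM + 1) 72 fell at 32h, where the median of all genes on that scale was itself -0.17. Most libraries of the rarer naming style were at 0h or 8h, so the naming fit can hardly separate a batch from these late times. Without 32h replicate 5, 8 fell at 32h. The median log2 fold change at 56h was -0.41 (adjusted p = 0.833 with an estimated correlation). Genes of differentiated epithelium and mucus secretion were higher on average at these times. Their list score ran from -0.69 to 0.79 at 0h, and 32h replicates 3 and 4 and 56h replicates 2 and 3 lay within that range. Of the 16h libraries only replicate 2 lay above it, and of the 7d libraries only replicates 1 and 2. Of 39 members 26 rose and 1 fell at 32h, 26 and 1 adjusted over the list alone, with a median of 1.19, and 22 rose and 2 fell at 56h, 22 and 3 adjusted over the list alone (adjusted p = 0.525 and adjusted p = 0.56 with an estimated correlation). KRT20, a keratin of differentiated gut epithelium, went from 327 ± 117 CPM at 0h to 1410 ± 573 at 32h, KRT19 from 1300 ± 135 to 3630 ± 451 and CAPN8 from 93.8 ± 31.2 to 339 ± 68.1 CPM. LYZ, the lysozyme gene, was the member that fell at 32h, from 3540 ± 227 to 1560 ± 378 CPM. In the unfolded protein response list 15 of 24 rose at 32h and 12 at 56h, 16 and 13 adjusted over the list alone (adjusted p = 0.442 and adjusted p = 0.622 with an estimated correlation). Replication-dependent histone genes, whose transcripts mostly lack a polyA tail, rose in 7 of 12 cases at 32h, 9 adjusted over the list alone (adjusted p = 0.851 with an estimated correlation). H1-2 went from 13.1 ± 6.5 to 34.3 ± 21.8 CPM and H2BC5 from 14.2 ± 5.92 to 36.9 ± 19.5, and members of this family share sequence, so their values are uncertain. Of the mitochondrially encoded genes 8 of 13 rose at 32h, 11 adjusted over the list alone (adjusted p = 0.851 with an estimated correlation). Interferon genes rose in 9 of 35 cases at 32h and 1 fell, also adjusted over the list alone (adjusted p = 0.865 with an estimated correlation), with a median of 0.22 by edgeR. Of the interferon genes 6 rose and 3 fell on log2(TPM + 1), with a median of -0.02, above the -0.17 of all genes on that scale. Cholesterol synthesis genes rose in 8 of 24 cases at 32h and in 12 at 56h, 4 and 13 adjusted over the list alone (adjusted p = 0.917 and adjusted p = 0.769 with an estimated correlation). Without the libraries of RIN under 7, 4 cholesterol synthesis genes and 4 histone genes rose at 32h. Without 32h replicate 5, 4 cholesterol synthesis genes and 5 mitochondrially encoded genes did. On log2(TPM + 1) the 32h numbers were 2 for cholesterol synthesis, 4 for histones, 4 for mitochondrially encoded genes and 9 for the unfolded protein response.

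By the same rule the largest rises at 32h and 56h were in ACHE, PSCA, SMIM5, RAB37, LGALS2 and HAL, and in CST4, B3GALT2, ACHE, PSCA, CST1 and B3GNT6. PSCA, a surface antigen of secretory epithelium, went from 49 ± 43.4 CPM at 0h to 567 ± 454 at 32h and 590 ± 252 at 56h. CST1, a salivary cystatin, went from 6.23 ± 2.26 to 68.4 ± 9.76 CPM at 56h (adjusted p = 8.31e-07), and CST4 from 0.235 ± 0.115 to 8.51 ± 1.52. CST1 and CST4 are close paralogs, so reads could be split between them. B3GALT2 and B3GNT6, glycosyltransferases, reached 9.57 ± 3 and 10.6 ± 4.06 CPM at 56h. Besides the Wnt targets, the largest falls by that rule at 32h were in ATOH8, EDAR and SLC34A2, and at 56h in ATOH8, ALDH3A1 and DHRS2. ATOH8, a helix-loop-helix transcription factor, went from 6.55 ± 1.72 to 0.328 ± 0.2 CPM at 56h, and ALDH3A1, an aldehyde dehydrogenase, from 30.2 ± 12 to 1.91 ± 0.602 CPM.

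At 7d all 46 S phase and all 41 G2/M genes fell, also adjusted over the list alone, with medians of -1.25 and -2.03 (adjusted p = 0.483 and adjusted p = 0.254 with an estimated correlation). By fry these lists had adjusted p = 1.05e-05 and adjusted p = 9.93e-08. Homologous recombination genes fell in 29 of 35 cases (30 adjusted over the list alone; adjusted p = 0.483 with an estimated correlation). MYC targets fell in 37 of 55 cases and ribosome biogenesis genes in 38 of 57 (40 and 40 adjusted over the list alone; adjusted p = 0.68 and adjusted p = 0.779 with an estimated correlation). RPL12 went from 424 ± 44.9 to 254 ± 69.1 CPM and RPS19 from 297 ± 43.2 to 179 ± 53 CPM (list adjusted p = 0.674 with an estimated correlation). Genes of ribosomal proteins have many processed pseudogenes, so their counts depend on how shared reads were assigned. Of 44 mitochondrial ribosome genes 23 fell, 23 adjusted over the list alone (adjusted p = 0.851 with an estimated correlation), and of 47 oxidative phosphorylation genes 12 fell, 11 adjusted over the list alone (adjusted p = 0.865 with an estimated correlation). UQCRC2, a subunit of complex III, went from 164 ± 14.5 to 107 ± 20 CPM. With naming style as a covariate 11 mitochondrial ribosome genes and 6 oxidative phosphorylation genes fell, while 25 oxidative phosphorylation genes did on log2(TPM + 1) and 23 without 7d replicate 6.

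Interferon genes were below 0h at 7d, with 19 of 35 lower and 3 higher (19 and 3 adjusted over the list alone) and a median of -0.50 (camera adjusted p = 0.000239; adjusted p = 0.828 with an estimated correlation). Of 20 YAP target genes 11 rose and 4 fell, and 11 and 4 adjusted over the list alone (adjusted p = 0.649 with an estimated correlation). IGFBP3 went from 375 ± 53.7 to 1100 ± 237 CPM (adjusted p = 5.66e-10) and TGFB2 from 98.2 ± 24.7 to 248 ± 65.7 CPM. FOXF2 fell by 1.00. Cholesterol synthesis genes rose in 14 of 24 cases and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 0.793 with an estimated correlation), with a median of 0.39. With RIN as a covariate 8 rose and the median was 0.26, and 9 rose on log2(TPM + 1). Of the epithelial genes 16 of 39 rose and 4 fell (16 and 4 adjusted over the list alone; adjusted p = 0.835 with an estimated correlation). The largest rises at 7d by the rule were those of CST4, B3GALT2, ACHE, KRT16, PSCA and CST1. ACHE, acetylcholinesterase, went from 2.81 ± 2.3 to 63.6 ± 34.7 CPM and KRT16, a stress keratin, from 0.343 ± 0.229 to 6.15 ± 3.65. The largest falls by the rule besides NOTUM, AXIN2 and NKD1 were those of ATOH8 (-5.01), ALDH3A1 (-4.20) and DHRS2 (-4.04).

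Treated times were also compared with each other, as contrasts of the same fit of 43 libraries, so the 0h libraries enter through the shared spread. Between 3h and 8h 38 genes were higher at 8h and 60 lower. By the rule for named genes (protein-coding, at least 5 CPM in the higher group and groups that do not overlap) the largest rises were those of IFIT1 (223 ± 47.2 to 419 ± 75.7 CPM), ETV7, USP18 and IFIT2. Among the falls by that rule, FGF19, an endocrine growth factor, went from 30.6 ± 10.2 to 11.1 ± 2.33 CPM, and PTCH1, the Hedgehog receptor, from 15.4 ± 3.36 to 7.63 ± 1.18 CPM (adjusted p = 0.00024), with ZNF703 and PCDHGA4 next. Without the library labelled 3h replicate 6 the numbers were 48 and 95, and without the libraries of RIN under 7 they were 2 and 6, with IFIT1 at an adjusted p = 0.0652, within 0.000526 and 0.0652 over its alternatives. On log2(TPM + 1) they were 8 and 235, with the median of all genes at -0.13. The 98 genes became 12 with only the libraries of 3h and 8h in the fit, 27 with RIN as a covariate and 37 with naming style. Adjusted p went up to 0.111 for USP18, 0.0997 for IFIT2, 0.263 for ETV7 and PCDHGA4 and 0.0705 for ZNF703 over their alternatives. The 98 became 62 without 3h replicate 1, 54 without 3h replicate 2, 57 without 3h replicate 5, 57 without 8h replicate 4 and 42 without 8h replicate 5. PCDHGA4 shares its last exons with other genes of its cluster. Between 8h and 56h 2670 genes were higher at 56h and 3123 lower. The rule took CST4, B3GALT2, ACHE and CST1 among the rises and NOTUM, DHRS2, ALDH3A1 and MYBL2 among the falls, and MYBL2, a transcription factor of the cell cycle, went from 100 ± 9.73 to 10.7 ± 2.34 CPM. On log2(TPM + 1) 4475 genes were higher and 1502 lower at 56h, with the median of all genes at 0.14.

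Between 56h and 7d 202 genes were higher at 7d and 143 lower. Of the genes the rule took, NNMT, a methyltransferase of nicotinamide, went from 1.8 ± 0.276 to 7.63 ± 3.03 CPM, and CXCL14, a chemokine, from 5.57 ± 2.22 to 13.9 ± 4.88. MYBL1, a transcription factor, went from 3.29 ± 0.676 to 11.2 ± 2.48 CPM (adjusted p = 0.000466) and CENPH, a kinetochore gene, from 2.13 ± 0.229 to 5.22 ± 2.04 (adjusted p up to 0.0872 over the alternatives of CENPH). CCND1 was 0.63 higher on the log2 scale at 7d than at 56h and PORCN 0.46 higher. MUC6, a gastric mucin, went from 22.1 ± 4.58 to 3.94 ± 2.21 CPM (adjusted p = 0.000466), with ELAPOR1, AKR1C2 and ADIRF also lower. AKR1C2 has near-identical paralogs. The total of 345 genes was 186 without 7d replicate 4, 202 without 7d replicate 3, 189, 216, 193 and 220 without 56h replicates 1, 2, 3 and 4, and 518 without the library labelled 3h replicate 6. DESeq2 called 522 genes.

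Markers of other cell types in the pancreas took small shares of the counts. The host was a mouse and reads were counted on hg38, so these shares do not measure host cells. Expression in the tumour cells and misassigned mouse reads could not be told apart. Genes of acinar cells took 0.000649% of counts at 0h and 0.00138% at 7d, above all 7 vehicle libraries in 6 of 6 (exact two-sided permutation p = 0.000583, adjusted p = 0.00629), the smallest p that 7 against 6 libraries can give. PRSS2, a trypsinogen, had 1.33 CPM at 0h and 5.86 CPM at 7d (log2 fold change 2.14, adjusted p = 0.000105); it has close paralogs. Islet genes took 0.00141% at 0h, 0.00111% at 8h, below all vehicle libraries in 6 of 6 (exact permutation p = 0.00291, adjusted p = 0.0157), and 0.00196% at 7d, above all of them in 5 of 6 (exact permutation p = 0.00117, adjusted p = 0.00899). Without the libraries of RIN under 7 the fall at 8h did not pass (exact permutation test, adjusted p = 0.0595). SCG2, a granin, had 1.39 CPM at 0h and 8.48 CPM at 7d. PRSS2 and SCG2 were chosen after their values were seen. Stroma genes went from 0.00737% to 0.00506% at 56h, below all vehicle libraries in 5 of 6 (exact permutation p = 0.0035, adjusted p = 0.0172). As a share of summed TPM this fall did not pass (exact permutation test, adjusted p = 0.272). Leukocyte genes went from 0.384% to 0.102% at 7d, below all vehicle libraries in 6 of 6 (exact permutation p = 0.000583, adjusted p = 0.00629), but LYZ gave between 97.3% and 98.3% of that share at 0h, and without LYZ the shares were 0.00829% and 0.0137%. Endothelial genes took 0.00163% at 0h and 0.00125% at 7d (exact permutation p = 0.0175, adjusted p = 0.0787). Erythroid genes took 4.32e-06 percent at 0h and 4.36e-06 percent at 7d (exact permutation p = 0.994, adjusted p = 1.0). The mitochondrially encoded share was 6.13% ± 1.04 (SD, n = 7) at 0h and 9.9% ± 4.36 (n = 6) at 8h (exact permutation p = 0.0227, adjusted p = 0.0877). Library totals did not pass at any time, and 11 of 54 tests passed. Fewer than 5 members of the acinar, islet, endothelial and erythroid lists were measured, so camera was not run on them.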

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

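The tests of the library labelled 3h replicate 6, the RIN tests of mitochondrial transcripts and the test of interferon genes with RIN as a covariate were chosen after the results were seen, while the other interferon tests, the naming tests and the splits were planned. Standing apart means that a library's gap to its nearest neighbour was a large part of its group's range, which chance gives in about 1 of 20 groups. This was met in 7 of 70 groups for the fixed Wnt genes, 20 of 224 for list scores, 1 of 63 for library measures and 110 of 910 for all named genes.

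The library labelled 3h replicate 6 stood apart in 49 named genes. It had 0.168 CPM of NOTUM and 2.6 CPM of AXIN2, and its list scores were -1.51 for Wnt targets, -2.18 for S phase, -2.29 for G2/M, -1.66 for homologous recombination, -0.53 for MYC targets and -0.33 for ribosome biogenesis. Its score of islet genes was 0.99 and its share of stroma genes 0.00434%. An exchange with a later library would leave a high Wnt target score among the 24 libraries labelled 16h or later, but the highest was -1.31, against -0.24 to -0.02 in the other 3h libraries. Its RIN of 8.4 lay within the 8.2 to 9.4 of its group, which argues against low RNA quality, and a response of Wnt targets alone is argued against by the G2/M score of -2.29. Over all tested genes its deviations correlated best with the 56h group (0.68 across genes, which are not independent replicates; -0.55 with its own group), which is consistent with a tumour taken later than its label says. By this measure 26 of 43 libraries were nearest to their own group, and of the other 5 at 3h 4 were nearest to 0h and 1 to 8h, so it does not resolve neighbouring times, but 3h replicate 6 was the 1 of 19 libraries labelled 0h, 3h or 8h nearest to a group of 16h or later. A single wrong label and a sample from outside the series both stay open.

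Mitochondrially encoded genes were higher at 8h, with a median log2 fold change of 0.81. With naming style as a covariate the median was 0.86 and 13 genes passed, which argues against a batch marked by naming. Mean RIN was 7.47 in both groups, so a linear trend with RIN would give little difference between them, which argues against it as the whole cause. For the same reason the fit with RIN as a covariate could hardly move the value and adds no separate support. Its median was 0.73 and 13 genes passed. Without the libraries of RIN under 7 the median was 0.45 and 0 genes passed, with 4 libraries left at 8h. The share of these genes was 11.7%, 17.5% and 10.4% in 8h replicates 3, 4 and 5, which had the lowest RIN at 8h (7.1, 6.2 and 5.6). In 8h replicates 1, 2 and 6 it was 5.85%, 7.0% and 6.97%, within the 4.58% to 7.6% of 0h. The higher share at 8h thus rests on the 3 libraries of lowest RIN, although 0h replicate 5, also with a RIN of 7.1, had 5.83%. What low RIN adds cannot be told apart from an effect of the time, and a biological difference at 8h stays open.

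Interferon response genes were higher on average at 8h, with a median of 0.42 and 17 genes called. The list scores of 8h replicates 4 and 6 lay within the range of 0h. Without the libraries of RIN under 7 the median was 0.46 and 9 genes passed, and with naming style as a covariate it was 0.37 and 17 passed. With RIN as a covariate it was 0.42 and 17 passed, but mean RIN was 7.47 at 8h and at 0h, so that fit could hardly move the value. The first 2 values argue against RIN under 7 and naming as the whole cause. On log2(TPM + 1) 5 of the 35 genes passed, and without 8h replicate 3, 11 did. Camera with an estimated correlation gave an adjusted p = 0.343, and fry gave an adjusted p = 0.00378. The time on ETC-159 and handling at that time stay open, since no vehicle group was sampled at 8h.

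The library 16h replicate 2 stood apart in 22 named genes. Its list scores were -1.9 for Wnt targets, -1.06 for MYC targets, -0.78 for ribosome biogenesis, -0.62 for mitochondrial ribosome, 0.74 for CDK inhibitors and 0.18 for p53 targets, and ZNRF3 was at 3.45 CPM. Its deviations correlated best with the 32h group (0.37 across genes; -0.17 with its own group). In 56h replicate 1 the scores were -0.94 for MYC targets and -0.64 for ribosome biogenesis, with CCND1 at 186 CPM. CCND1 was at 296 CPM in 0h replicate 7, PORCN at 26.3 CPM in 16h replicate 5 and AXIN2 at 0.355 CPM in 56h replicate 6. The MAPK feedback score was 0.11 in 3h replicate 3 and -0.01 in 32h replicate 5. The hypoxia score was 0.76 in 8h replicate 3, the islet score -0.59 in 8h replicate 2 and the immediate early score 0.29 in 7d replicate 6.

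Fixed Wnt genes also differed between treated times by edgeR's test of the contrast itself. From 3h to 8h the log2 changes were -1.59 for AXIN2 and -1.58 for NKD1. The library labelled 3h replicate 6 was in the 3h group of this contrast. Without it the 3h means were 21.8 CPM for AXIN2 and 40.5 CPM for NKD1, against 18.6 and 34.5 with it. Which fixed genes passed from 3h to 8h may therefore depend on that library. From 8h to 56h they were -4.65 for NOTUM, -2.70 for AXIN2, -2.06 for NKD1, -1.55 for LGR5, -0.84 for RNF43, -0.79 for ZNRF3, -0.79 for MYC and -0.46 for CCND1. From 56h to 7d they were 0.63 for CCND1 and 0.46 for PORCN.

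Each count of genes was set against 50 splits of the libraries into groups of the same sizes, of which 1, the real one, gave as many. With 50 splits the share cannot fall below 1 in 50, so chance is made less likely but is not excluded. Another split came nearest the real count at 8h. At 32h, at 56h and for 8h against 3h the highest other split was also a large part of the real count. The real counts and the highest of the other splits were 4 and 0 at 3h, 1506 and 1218 at 8h, 3128 and 1115 at 16h, 7555 and 4402 at 32h, 7010 and 4310 at 56h, and 7571 and 613 at 7d. They were 10359 and 1868 at any time, 98 and 62 for 8h against 3h, 5793 and 2272 for 56h against 8h, and 345 and 0 for 7d against 56h. The median of the other splits was 0 in each comparison.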

How the results depend on the processing

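The leave-outs of single libraries were chosen after the results were seen, and the other alternatives were planned. Over 10 alternatives 1984 of 2060 values of named genes kept their side of the threshold, 62 lost the call, 14 gained it and 0 reversed. The 1984 include 10 sign changes of values that passed in neither fit. Apart from the fixed Wnt genes, named genes were chosen as called in the main fit. Their stability therefore does not describe called genes at large. The cause was not tested where a count moved, except where fewer libraries or genes were used.

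At 3h the 4 genes became 1 with RIN as a covariate, 12 with naming style, 32 with DESeq2, 2 with limma on log2(TPM + 1), 0 with only the groups compared and 1 with a log2 change of at least 1. At 8h the 1506 genes became 914 without a filter on low counts, 2371 with naming style, 419 without RIN under 7, 4098 with limma on log2(TPM + 1), 298 within 1 naming style (3 libraries against 6) and 141 with the minimum change. At 16h the 3128 genes became 2060 with naming style and 500 with the minimum change, which left 1717 at 32h, 1672 at 56h, 1861 at 7d and 1233 for 56h against 8h. For 8h against 3h the 98 genes became 62 without a filter, 27 with RIN, 37 with naming style, 8 without RIN under 7, 229 with DESeq2, 243 with limma on log2(TPM + 1), 12 with only the groups compared and 15 with the minimum change. For 7d against 56h the 345 became 202 without a filter, 522 with DESeq2, 173 with limma on log2(TPM + 1) and 109 with the minimum change. With an estimated correlation 1 list held at each time, and fry called 3 lists at 3h and 17 at 56h. Lists that did not hold with an estimated correlation could thus still pass by fry.

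Leaving out 1 library gave 1 to 15 genes at 3h, 779 to 1832 at 8h, 2284 to 3357 at 16h, 6744 to 7846 at 32h, 6106 to 7367 at 56h, 6608 to 7923 at 7d, and 9862 to 10793 at any time. It gave 42 to 145 for 8h against 3h, 4810 to 6243 for 56h against 8h, and 186 to 518 for 7d against 56h. Lists numbered 10 to 13 at 3h, 10 to 13 at 8h, 8 to 11 at 16h, 12 to 14 at 32h, 11 to 12 at 56h and 14 to 15 at 7d without 3h replicate 6 or 16h replicate 2. Leaving out each of the other 7 libraries that stood apart in a list score kept 210 of 213 values of named genes at their own time and ended 3 calls, those of PORCN and RNF43 at 8h and of HK2 at 16h.

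With the replicate number as a block 0 genes passed at 3h, and no other count moved by over 1.5 times. Of the values of named genes 5 lost the call by edgeR and 1 gained it. Those lost included RNF43 at 8h (adjusted p = 0.0522) and CXCL14 for 7d against 56h (adjusted p = 0.0547). The replicate numbers did not pair the libraries, since correlations of same-numbered libraries lay between -0.56 and 0.55 and at most 4 of 6 pairs were over 0.1. At most 2 libraries correlated best with their own number. Depth limits genes of low CPM, such as NOTUM at 0.175 CPM at 7d.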

Other observations

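The tests of clock genes and of S phase against mitotic genes were chosen after the results were seen, and the lists were planned. Immediate early genes rose in 9 of 19 cases at 32h, also adjusted over the list alone (camera adjusted p = 0.0775), and in 3 on log2(TPM + 1), among them FOS, from 87.7 to 162 CPM, and JUND, from 64.9 to 127 CPM. Of 20 p53 targets 4 rose and 8 fell at 7d, also adjusted over the list alone (camera adjusted p = 0.122), with MDM2 falling from 109 to 61.7 CPM. Notch targets went both ways at 7d, with 6 of 15 higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.987), and 3 lower with naming style as a covariate. NOTCH3 fell by 1.33 and MFNG rose by 1.54 on the log2 scale. Of 14 mesenchymal genes 5 rose and 2 fell at 32h, also adjusted over the list alone (camera adjusted p = 0.473), and SNAI2 went from 12.9 to 23.3 CPM. Of 30 lysosome and autophagy genes 11 rose and 2 fell at 7d, also adjusted over the list alone (camera adjusted p = 0.053), and CTSD went from 865 to 1397 CPM. The stroma list had 0 of 7 genes higher and 3 lower at 56h, and the leukocyte list 2 of 6 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.611 and 0.732). Genes of these paragraphs outside the rule were chosen after their values were seen.

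Of 21 circadian clock genes 7 rose and 7 fell at 16h, with 8 and 7 adjusted over the list alone (camera adjusted p = 0.521), and 4 and 4 with naming style as a covariate. Without 16h replicate 2 the numbers were 4 and 7. Against the mean of 8h, 32h and 56h, which share an elapsed hour of the day, 4 of 9 genes of the output arm fell at 16h (median -0.37) and 4 of 6 of the opposite arm rose (median 0.46). PER3 was at 7.45 CPM at 16h, against 17.6 at 8h and 16.6 at 32h, and BMAL1 at 19.4 CPM against 8.31 and 11.4. The arms differed by -0.84, which is consistent with a time of day that differs between these groups. The arms were drawn up after PER3 and TEF had been seen, the labels give no clock time, and an effect of ETC-159 on the clock stays open.

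At 16h S phase genes were lower and G2/M genes were not. The S phase score minus the G2/M score was -0.69 at 16h (SD 0.14, n = 6) and 0.0 at 0h (SD 0.06, n = 7; exact two-sided permutation p = 0.000583, the smallest possible, adjusted p = 0.00175 over 6 times). It was -0.65 without 16h replicate 2 (exact permutation p = 0.00126), -0.02 at 3h (exact permutation p = 0.691), -0.22 at 8h, -0.31 at 32h (SD 0.29; exact permutation p = 0.00932, adjusted p = 0.0112), 0.35 at 56h and 0.58 at 7d. Genes of S phase may fall before those of mitosis as cells leave the cycle, a hypothesis found and tested on the same libraries.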
